A study of Drosophila melanogaster with 2 samples.

How the data were processed

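Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos of both sexes, collected 0 to 16 h after egg laying per the labels. The fly line carries an artificial exon coding for eGFP inside an intron of ADD1, so that an ADD1-GFP fusion protein is made from the gene's own locus. The precipitation used an antibody against GFP per the sample descriptions. A separate antibody field in the labels names CG8290, the systematic name of ADD1. Chromatin was sheared by sonication to 200 to 800 bp. The 2 libraries form 1 group and are biological replicates, numbered 1 and 3 in the labels. The series holds no second group, and control libraries were not analysed here, so no difference between conditions was tested.

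The data are peak lists in narrowPeak format. Per the deposited file lists, the authors called peaks and background with a shared control file. Calls were made on each replicate's alignment and on the pooled alignments of both replicates. They were passed to the irreproducible discovery rate procedure (IDR), which compares the ranks of regions between replicates. The deposited thresholded list is called the kept peaks here. The aligner and the peak caller are not given in the sources used here. The signal value of each call was computed by the authors' caller and deposited as such. Its scale depends on the library, so it was used only to rank calls within a list. The deposited −log10 q-value saturates at a highest value per list and was used only to describe the lists. Every call list holds 30000 regions, for dm6 and for dm3 alike. Read numbers were not analysed here, so the depth of each library is unknown, and neither a floor nor an interval for the signal can be given.

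The kept peaks were identical to the 4402 pooled dm6 calls with the highest signal. Each test of kept peaks against the other pooled calls therefore compares strong with weak calls of the same list, and the p-values treat calls as independent, although neighbouring calls can overlap. The 4402 kept peaks form 4190 separate stretches. Neither p-values nor intervals cover variation between embryo collections. Intervals on shares and odds ratios are 95% exact intervals (Clopper-Pearson for shares, conditional for odds ratios) and cover counting error only.

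Coordinates are 1-based on dm6. Sequence came from the Release 6 assembly, and genes from the Ensembl release 115 annotation (18277 genes and 24111 transcription starts on the chromosome arms, transposable elements apart). A call was placed by its summit, as promoter (within 500 bp of an annotated start), else exon, else intron, else intergenic. Pericentric sequence was set by fixed boundaries, namely beyond 22 Mb on 2L, 23 Mb on 3L and 22 Mb on X, and before 5.6 Mb on 2R and 4.2 Mb on 3R. Chromosome X means the arm outside that part. A call counted as masked when most of the 100 bp on either side of its summit was soft-masked. The same window served for GC content and for 13 fixed motifs, read on both strands. A total of 17 gene lists were fixed before the data were examined, as were the motifs, the boundaries and all tests not named below as later choices.

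Shares, motifs and gene lists were compared with two-sided Fisher's exact tests, and mean GC content with a two-sided permutation test of 100000 resamples. P-values were adjusted by the Benjamini-Hochberg method over 10 tests of position and GC content, over 13 motifs and over 17 lists, at a threshold of 0.05. The smallest Fisher p written is 1e-300. For gene lists the background was the 8134 genes with any pooled call within 500 bp of a start. Replicate calls matched when they overlapped by at least 50% of the shorter one. Where several calls matched, the call with the largest overlap was taken. For ranks of named peaks the strongest matching call was taken instead, a choice made after the data were seen.

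Named genes followed a rule fixed beforehand. They are ADD1, the genes with the nearest start to the 25 strongest kept peaks (with the gene holding the summit where it differs), up to 4 members per list with the strongest kept promoter peak, and the genes nearest to the 4 strongest kept peaks of each region class that passed its test.

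Alternatives were the stronger part of the kept peaks by signal, the top 4402 calls of each replicate alone, random genome positions or all annotated genes as background, boundaries moved by 0.5 Mb, promoters of 200 or 1000 bp, the middle of the peak, other masking and window rules, other matching rules, and the dm3 lists. Alternatives added after the data were seen are promoter calls alone, calls outside promoters, GC-matched backgrounds, 1 call per run of overlapping calls, the strongest-match rule, permuted kept labels for the gene lists, and the share of summits in annotated transposable elements.

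The tests were checked on simulated labels. With kept labels drawn at random among the 30000 calls 100 times, 4.86% of share and motif tests had p under 0.05. For gene lists this share was 7.81%, above the nominal level, for a cause that was not tested. Gene lists were therefore also tested by permuting the kept labels among promoter calls 100000 times. A planted promoter odds ratio of 2 was recovered as 2.02 ± 0.0561 (SD, 20 draws), and a planted set of 200 among 8134 genes was found in 100% of 20 draws. Calls in that gene set simulation were kept more often than in the data. Its planted odds ratio per call was also larger than 2, so it gives no power at an odds ratio of 2. The lists tested here held from 4 (hemocyte) to 196 (tRNA) genes with a call, so it gives no power for small lists. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.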

Results

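Binding of ADD1, known as a heterochromatin protein related to the ADD domain of mammalian ATRX, was mapped by anti-GFP ChIP-seq in whole embryos of a line with a GFP-tagged endogenous ADD1. The single group held 2 biological replicates. Each replicate's list held 30000 dm6 calls, with a median signal of 23.2 in replicate 1 and 22.9 in replicate 3, and maxima of 647 and 805. The authors' IDR threshold kept 4402 dm6 peaks with a median width of 424 bp. They covered 1.70 Mb and had signal values of 96.4 to 1451, as scored by the authors. The depth of the libraries is unknown.

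Most of the strongest ADD1-GFP calls of replicate 1 were also among the strongest of replicate 3. Of the 4402 strongest calls of replicate 1, 3310 (75.2%) matched a call among the 4402 strongest of replicate 3. Of the 4402 kept peaks, 4369 (99.3%) matched a call in both replicates. A smaller number, 3253 (73.9%), matched a call among the 4402 strongest of both, so not every kept peak was a top call in each replicate. Among the 17501 calls of replicate 1 that matched any call of replicate 3, the odds of being a top call in replicate 3 were 32.4 times higher for top calls of replicate 1 (interval 29.5 to 35.6, two-sided Fisher's exact test, p below 1e-300). Across these matched calls Spearman's rho of the signal was 0.671, a description across regions, which are not independent replicates. Both replicates were called with a shared control file, and the overlap that this alone would give was not estimated.

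The strongest peaks lay mostly at gene starts. Of the 25 strongest, 17 had their summit within 500 bp of an annotated start. The summits of 13 were outside genes, 7 were in introns, 4 in untranslated regions and 1 in another exon. The peak with the highest signal (1451, ranked 1 in the pool and in both replicates) was on 2R from 22514114 to 22514489, in an intron of px (plexus, a wing vein patterning gene), 206 bp from a start. It was followed by peaks upstream of Ugalt, a UDP-galactose transporter gene (X, 2703703 to 2704067, signal 1271), and of CG14100 (3L, 19590435 to 19590805, signal 1233). The peak ranked 4 lay in an intron of ush, which codes for a GATA cofactor, with cbt as the gene of the nearest start (2L, 480910 to 481285, signal 1135). Chro, which codes for the chromodomain protein Chromator, had a peak in its 5′ untranslated region (3L, 22878725 to 22879098, signal 1022). Others among the 25 were next to Vha55 (a proton pump subunit, signal 834), Lk6 (a protein kinase, in an intron, 816), cno (the adherens junction protein Canoe, in an intron, 807) and CycB (cyclin B, 3334 bp from its start, 719). All 25 ranked within the top 100 of each replicate, the lowest rank being 39 in replicate 1 and 45 in replicate 3, although ranks in the pool are made from the same reads.

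The ADD1 locus itself carried strong peaks. The gene spans 2R from 11970686 to 11977721 on the plus strand, and 4 calls, all kept, lay within 2500 bp of it. The strongest (11970034 to 11970503, signal 775, rank 19) had its summit between ADD1 and the divergent gene PI31, a proteasome regulator, 324 bp from the ADD1 start. The next (11970401 to 11970820, signal 480, rank 107) overlapped it, with a summit 123 bp from the ADD1 start. The other peaks, at ranks 451 and 2241, were in an intron of PI31. The summits inside ADD1 numbered 0.

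**Figure D1:**
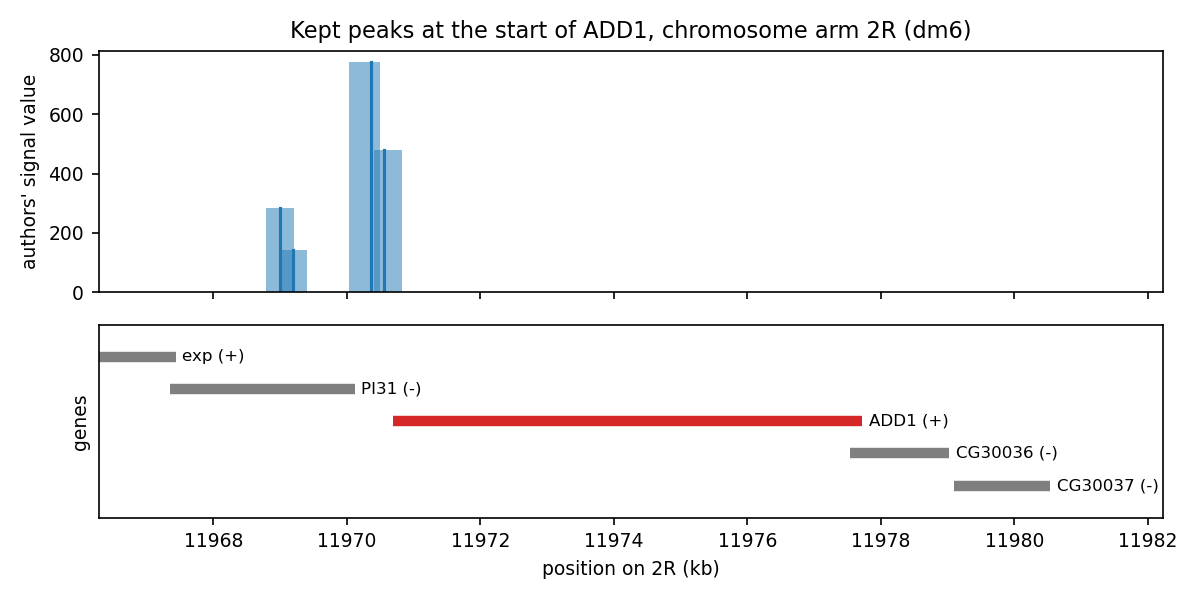
Kept peaks around the start of ADD1 on 2R (dm6), with the authors' signal value on the y axis of the upper panel and position in kb on the x axis. Filled boxes span the peaks, vertical lines mark summits, and bars in the lower panel are genes with their strand (exp runs beyond the left edge). The 4 peaks, with signal values from 143 to 775, have their summits upstream of ADD1.

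Kept peaks were concentrated at gene starts relative to weaker calls of the same list. Promoters held 59.8% of kept peaks (2634 of 4402, interval 58.4 to 61.3%) and 25.6% of the other calls, against 13.5% of random genome positions. The odds ratio of kept against other calls was 4.32 (4.04 to 4.62, Fisher's exact test, p below 1e-300). Introns held 25.1% of kept peaks and 42.2% of other calls (odds ratio 0.458, exact adjusted p = 6.89e-107). Exons outside promoters held 3.50% and 11.0% (odds ratio 0.294, exact adjusted p = 1.23e-65), and intergenic sequence held 11.6% and 21.2% (odds ratio 0.488, exact adjusted p = 4.94e-54). The promoter share was 64.4% among the 500 strongest calls and 17.5% among the weakest 10000.

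**Figure D2:**
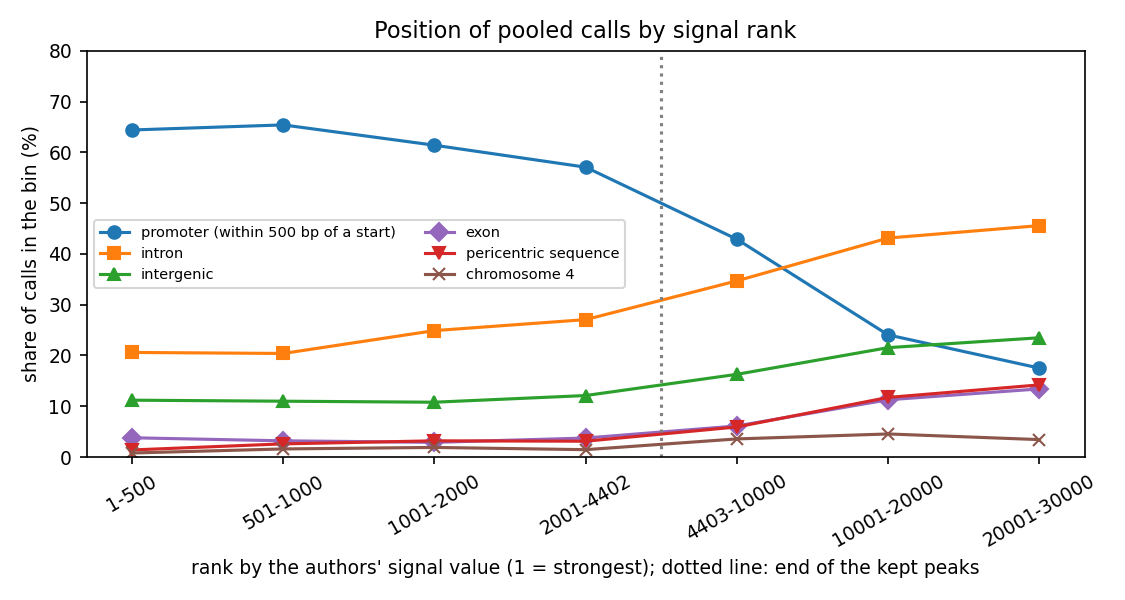
Share of pooled calls (y axis, %) in each position class by bins of signal rank (x axis, 1 is the strongest call). Points are shares of the calls in a bin, and the dotted line marks the end of the 4402 kept peaks. The promoter share goes from 64.4% in the first bin to 17.5% in the last, while the pericentric share goes from 1.40% to 14.2%.

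Pericentric sequence and chromosome 4, the small autosome with many heterochromatin marks, held a smaller share of the kept peaks than of the weaker calls. Pericentric sequence held 127 kept peaks (2.89%, interval 2.41 to 3.42%) and 11.4% of the other calls, with an odds ratio of 0.230 (0.191 to 0.276, Fisher's exact test, adjusted p = 5.43e-86). Chromosome 4 held 66 kept peaks (1.50%) and 3.90% of the other calls (odds ratio 0.375, 0.287 to 0.482, exact adjusted p = 4.13e-18). In density, however, chromosome 4 stood above the large arms. It had 790 calls per Mb, 3.50 times the 226 of the large arms outside pericentric parts, and 49.0 kept peaks per Mb, 1.33 times theirs. Pericentric sequence had 0.753 times their calls and 0.192 times their kept peaks per assembled Mb, but 2.36 and 0.796 times per Mb of sequence unique in the assembly. Against random genome positions the odds ratio of chromosome 4 was accordingly 1.66 (exact adjusted p = 5.12e-04). Among promoter calls alone, the odds ratio was 1.09 (0.821 to 1.44) for pericentric sequence and 0.730 (0.493 to 1.06) for chromosome 4, and neither passed the test.

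The strongest kept peaks on chromosome 4 had zfh2 (a zinc finger homeodomain gene, signal 390), the non-coding gene lncRNA:CR43437 (300.4), Asator (291, in its intron) and Gyf (287) as nearest genes. In pericentric sequence they were nearest to CG40191 (2R, 1243382 to 1243662, signal 372, 20610 bp away), MED21, a Mediator subunit gene (326), Haspin, a histone H3 kinase gene (319), and spok (310.3, 51519 bp away), a gene of ecdysone synthesis. Chromosome Y had 2 calls, neither kept. The share of 0 of 4402 allows up to 0.0682% by the limit of 3 counts and up to 0.0838% by the exact interval, for counting error only. How much of chromosome Y is unique in the assembly was not assessed. Its low counts therefore cannot tell a lack of binding from sequence where no call could be made. Chromosome X held 19.4% of kept peaks and 19.3% of other calls (odds ratio 1.00, 0.926 to 1.09, exact adjusted p = 1). This depended on the comparison, as chromosome X passed outside promoters (1.18, exact adjusted p = 0.00979) and against random positions (1.24, exact adjusted p = 4.12e-07).

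**Figure D3:**
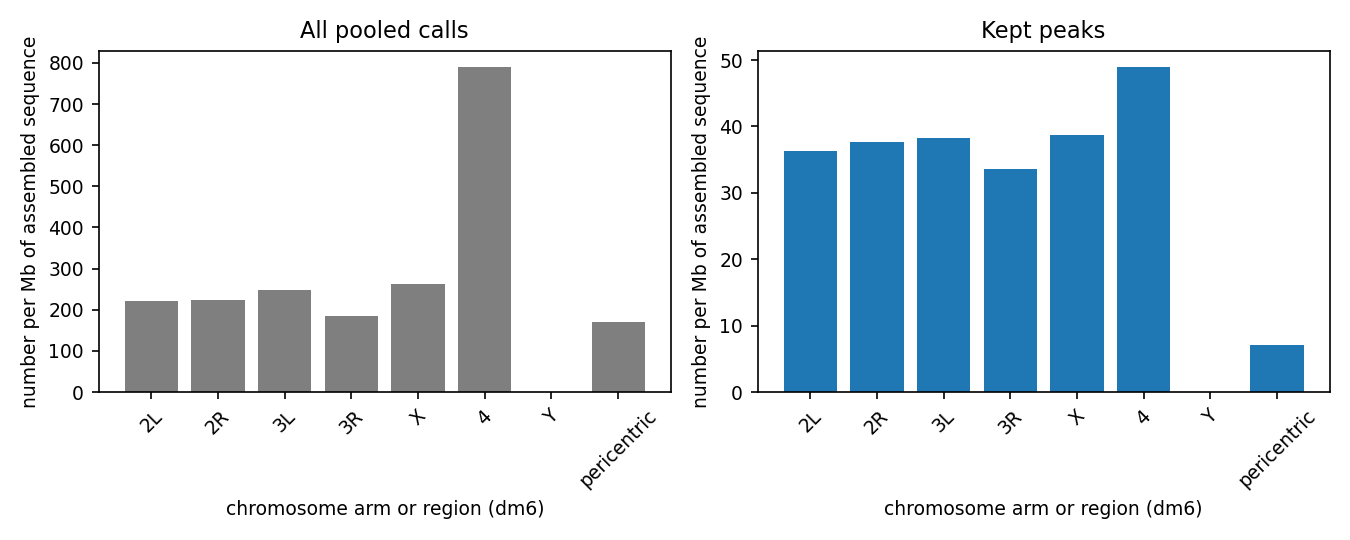
Number of pooled calls per Mb (left, y axis) and of kept peaks per Mb (right, y axis) for each dm6 chromosome arm outside its pericentric part, chromosomes 4 and Y, and the pooled pericentric parts (x axis). Chromosome 4 has 790 calls and 49.0 kept peaks per Mb, and pericentric sequence 170.0 and 7.07, per Mb of assembled sequence whether unique or not.

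Kept peaks also lay less often on repeats and were poorer in G and C. Masked windows made up 3.09% of kept peaks and 5.39% of other calls (odds ratio 0.559, 0.464 to 0.669, exact adjusted p = 1.44e-11). This odds ratio was 0.866 among promoter calls alone, where it did not pass, and 0.863 when a masked base at the summit decided. Summits inside annotated transposable elements, a comparison added after the data were seen, made up 0.386% of kept peaks (17) and 3.46% of other calls (886), with an odds ratio of 0.108 (0.0626 to 0.174, Fisher's exact test, p = 7.03e-41). It was 0.213 without replicate 3, 0.0381 for the stronger part of the kept peaks and 0.185 outside promoters. Windows unique in the assembly (all 32-mers within 100 bp of the summit occurring once) held 98.0% of kept peaks and 92.2% of other calls. Neither comparison of repeats was limited to such windows, so an effect of reads shared between copies was not set apart. Mean GC content was 37.2% ± 7.31 in kept peaks and 39.6% ± 7.87 in other calls (SD across 4402 and 25598 windows), against 42.1% at random positions. The permutation test gave p = 1e-05, the smallest that its resamples allow (adjusted p = 1.25e-05). The difference of kept minus other calls was -2.41 percentage points, and -1.29 with 200 bp on either side.

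Core promoter elements of broadly expressed genes were more frequent in kept peaks as a whole than in other calls, though not in every part of the ranking. Of 13 motifs, 5 were more and 2 less frequent than in other calls. The DRE octamer TATCGATA, bound by DREF and BEAF-32, was in 7.16% of kept and 2.17% of other windows (odds ratio 3.48, 3.01 to 4.02, Fisher's exact test, adjusted p = 7.16e-57). Its shorter core TCGATA was in 20.8% and 11.0% (odds ratio 2.13, exact adjusted p = 5.17e-65), and GGTCACAC, the M1BP element, in 4.50% and 1.65% (odds ratio 2.81, exact adjusted p = 1.92e-27). GGTATTT, a core promoter motif, had an odds ratio of 1.52 (exact adjusted p = 2.67e-09), which fell short of the threshold outside promoters (1.15, exact adjusted p = 0.334) and against promoter calls of matched GC content (1.16, exact adjusted p = 0.195). Among the 500 strongest calls the shares were 5.40% for DRE, 2.80% for the M1BP element and 5.20% for GGTATTT, against 4.68%, 3.63% and 5.93% in ranks 4403 to 10000 below the kept peaks. The arbitrary octamer ACGTTACG, included as a control, passed as well, with 20 kept and 49 other windows (odds ratio 2.38, 1.34 to 4.08, exact adjusted p = 0.00352), so that passing this test is not specific to promoter elements. The CA repeat (odds ratio 0.374, exact adjusted p = 4.47e-08) and the A tract (0.561, exact adjusted p = 5.98e-15) were less frequent, the CA repeat without passing outside promoters (0.575). With 200 bp on either side, the odds ratio of the CA repeat was closer to 1 (0.691), still passing. The GAGA repeat, the Zelda site, the E-box, the PHO site and the AATAT and AAGAG satellite units did not pass. The PHO site did pass, as less frequent in kept peaks, with 200 bp on either side (0.874, exact adjusted p = 0.0391) and against random positions (0.705). The GAGA repeat (odds ratio 0.995) passed in opposite directions under alternatives. It was less frequent in kept peaks among promoter calls (0.760, exact adjusted p = 0.0220) and more frequent with 200 bp on either side (1.28), against GC-matched calls (1.31) and against random positions (1.87). Against promoter calls of matched GC content its odds ratio was 0.995, without passing.

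Among promoter calls alone, DRE remained more frequent in kept peaks, with 11.0% against 5.40% (odds ratio 2.16, 1.83 to 2.55, exact adjusted p = 5.78e-19). Outside promoters, its odds ratio was 1.40 (0.889 to 2.12, exact adjusted p = 0.256), that of TCGATA 0.970 and that of the M1BP element 1.37, none of which passed. The control octamer did not pass in either part (1.91 at promoters and 2.36 outside), nor with the stronger part of the kept peaks (1.90).

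By gene group, kept promoter peaks were most frequent at ribosomal protein genes and least frequent at tRNA genes among the lists that passed. Of 8134 genes with any call at a start, 3473 (42.7%) had a kept peak. Among cytoplasmic ribosomal protein genes the number was 69 of 80 (86.3%, odds ratio 8.57, 4.49 to 18.0, Fisher's exact test, adjusted p = 5.65e-15), with RpS27 (signal 461), RpL7 (410.5), RpL23A (372) and RpL13A (365) the strongest. Housekeeping genes had kept peaks at 15 of 20 (75.0%, odds ratio 4.04, exact adjusted p = 0.0296), among them the glycolytic genes Gapdh2 (signal 302), Pgk (227) and Eno (226) and the translation factor gene eEF1alpha1. This call ended with the top calls of either replicate alone (odds ratios 3.08 and 3.39, exact adjusted p = 0.0639 and 0.0733), with the stronger part of the kept peaks (1.61) and with promoters of 200 bp (3.00, exact adjusted p = 0.0806). Of tRNA genes, 25 of 196 (12.8%) had a kept peak, an odds ratio of 0.190 (0.120 to 0.292, exact adjusted p = 8.45e-19). It was 0.376 without replicate 3, 0.114 with promoters of 200 bp and 0.305 with promoters of 1000 bp, and passed each time. Whether reads can be placed uniquely at tRNA genes was not examined. The low share therefore cannot tell weak binding from signal lost where reads could not be placed. Neighbouring genes can share a call, so genes of a list are not independent. With kept labels permuted among promoter calls, 68.2 tRNA genes were expected against 25 found (permutation test, adjusted p = 1.7e-04). For ribosomal protein genes 29.0 were expected against 69 (permutation adjusted p = 1.7e-04), and for housekeeping genes 8.90 against 15 (permutation adjusted p = 0.0315).

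The remaining lists did not pass Fisher's exact test as set, though several did under alternatives. Genes of pericentric heterochromatin had kept peaks at 14 of 20 (odds ratio 3.14, 1.13 to 9.98, exact adjusted p = 0.0843), including RpL38, Dbp80, Nipped-B and lt. With kept labels permuted among promoter calls, this list held 14 genes against 7.78 expected (permutation test, adjusted p = 0.0315), and with promoters of 200 bp its odds ratio was 3.88 (exact adjusted p = 0.0289). Chromosome 4 genes had them at 19 of 40, PlexA, RpS3A, PlexB and pho being the strongest. Genes of heterochromatin proteins had them at 12 of 22, including ADD1 (signal 775), the HP1a gene (191), Lhr (181) and HP4 (172). The odds ratio of that list was 1.61, and it was 1.07 without replicate 3 and 2.72 without replicate 1, none passing. The counts were 5 of 25 for early patterning genes (exact adjusted p = 0.0843), 3 of 17 for Hox and Polycomb target genes (exact adjusted p = 0.109), 2 of 14 for nervous system genes (exact adjusted p = 0.0920) and 1 of 10 for epidermis and cuticle genes (exact adjusted p = 0.109). With promoters of 200 bp, the odds ratio went from 0.335 to 0.172 for early patterning genes (exact adjusted p = 0.0289), from 0.287 to 0.115 for Hox and Polycomb target genes (exact adjusted p = 0.0305) and from 0.223 (2 of 14) to 0 of 11 for nervous system genes (exact adjusted p = 0.0205), written as 0.0598 only by adding 0.5 to each count. The first 2 rest on 2 of 18 and 1 of 13 genes. Early patterning genes also passed with 1000 bp (0.303, exact adjusted p = 0.0456). With the top calls of either replicate alone none of these 3 passed, at 0.375 to 0.537, 0.386 to 0.521 and 0.521 to 0.676. Kept peaks were at ph-p, a Polycomb group gene (signal 704, rank 26), and at elav, a neuronal RNA-binding protein gene (503, rank 85). The summit of the latter lay in an intron of arg, 271 bp from an elav start. They were at 9 of 13 germline, 4 of 9 glia, 8 of 21 muscle, 2 of 4 hemocyte, 5 of 10 gut and 6 of 13 heat shock genes. The odds ratio of heat shock genes was 1.15, and 4.07 and 5.02 with the top calls of either replicate alone, without passing. Against all annotated genes, the lists of pericentric genes (7.49), chromosome 4 genes (3.39), heterochromatin proteins (3.02) and germline genes (3.84) passed. None of the 111 replication-dependent histone genes had a call at its start, so that list was not tested on this background. Whether reads can be placed uniquely at these starts was not examined.

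**Figure D4:**
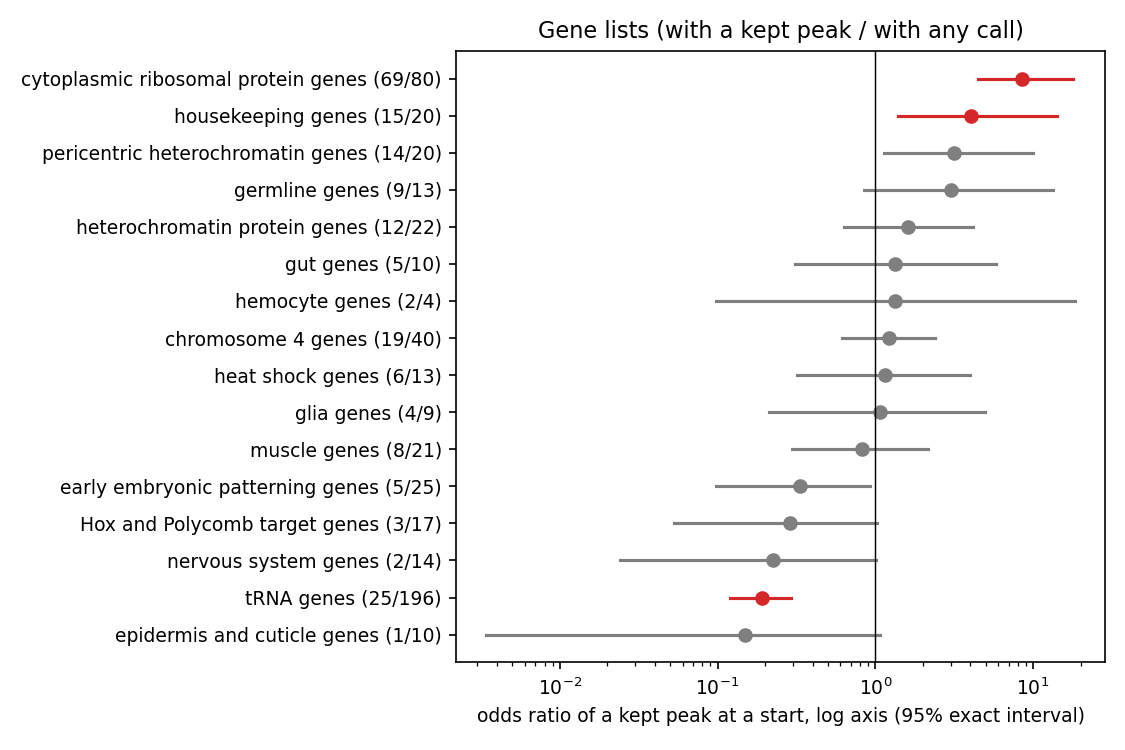
Odds ratio of a kept peak at a start (x axis, log scale) for each gene list with any call, against the other genes with a call. Points are odds ratios, lines 95% exact intervals, and red marks an adjusted p under 0.05. Ribosomal protein genes (8.57) and housekeeping genes (4.04) lie above 1, and tRNA genes (0.190) below.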

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

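Calls on sequence that no comparison used were seen only in the dm3 lists, whose assembly has unplaced scaffolds. There, 104 of the 30000 pooled calls lay on such scaffolds, above the 3 calls that a count of 0 allows. Of the 104, 2 were kept. Their median signal was 30.1, against 41.3 over all dm3 pooled calls, and the strongest ranked 1217. No annotation of these scaffolds was used here.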

How the results depend on the processing

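Across 45 results and 330 alternative values, 268 kept their direction and their side of the threshold (or stayed within the set range), 13 no longer passed, 15 newly passed, 5 values or counts moved and 29 odds ratios crossed 1. Of these 29, 22 passed on neither side, 2 passed only as reported, 4 only under the alternative and 1 under both. Choices made after the data were seen are the split by promoters, GC matching, runs of overlapping calls, the strongest-match rule and permuted labels. The cause was not tested unless stated.

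With random genome positions as background, the odds ratio became 1.66 for chromosome 4 (passing in both directions), 1.24 for chromosome X (newly passing), 0.00413 for chromosome Y (0.5 added to each count, which alone puts its reported value above 1), 1.87 for the GAGA repeat and 1.45 for AATAT. Among promoter calls alone it became 1.09 for pericentric sequence, without passing, 0.730 for chromosome 4, 0.882 for chromosome X and 0.866 for masked windows. Outside promoters it became 1.18 for chromosome X, newly passing, 0.970 for TCGATA, without passing, and 1.16 for the GAGA repeat, and 1 motif passed in place of 7. Against GC-matched calls it was 1.31 for the GAGA repeat, 1.08 for the Zelda site and 1.05 for the E-box, and with 200 bp on either side 1.28 for the GAGA repeat and 1.08 for the E-box. For chromosome X it was 0.936 with the stronger part of the kept peaks and 0.985 in the dm3 lists.

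With the top calls of either replicate alone, the odds ratio was 1.03 to 1.10 for the GAGA repeat, 0.920 to 1.10 for the E-box, 0.727 to 1.94 for AATAT, 0.773 to 1.30 for muscle and 0.451 to 1.43 for hemocyte genes. Against all annotated genes it was 1.90 for muscle and 0.775 for hemocyte genes. With promoters of 200 bp it was 0.689 for hemocyte, 0.459 for gut and 0.689 for heat shock genes, and with promoters of 1000 bp 1.00 for muscle and 0.892 for hemocyte genes. For hemocyte genes it was 0.893 with the stronger part of the kept peaks. None of these gene list values passed.

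The number of gene lists that passed was 3, and 8 against all annotated genes and 6 with promoters of 200 bp (other lists that newly passed are named in the report). The 8 include the histone genes, which had no value on the reported background (0 of 111, odds ratio 0.0190 with 0.5 added to each count, exact adjusted p = 1.27e-09). Whether reads can be placed uniquely at these starts was not examined. This value therefore cannot tell a lack of binding from sequence where no call could be made. The stronger part of the kept peaks holds 2201 by construction. Spearman's rho between replicates was 0.738 with summits within 100 bp.

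Boundary shifts left the pericentric share on the same side, and promoter width and the middle of the peak did so for promoters, introns, exons and intergenic sequence. Overlapping runs and the top calls of either replicate alone left all shares of position and GC content on the same side. No dm3 call lay on chromosome Y, so that alternative gave no value. No paired analysis was possible because there is 1 group. The depth is unknown, so what it limits was not assessed.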

Other observations

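The tests of promoter composition and of the heptamers below were chosen after related values had been seen. The others were written before their results were seen, though the patterns themselves came from these data. Kept promoter peaks more often had annotated starts of both strands nearby. Starts on both strands within 500 bp of the summit were found at 1055 of 2634 kept (40.1%) and 1279 of 6559 other promoter calls (19.5%), an odds ratio of 2.76 (2.49 to 3.05, Fisher's exact test, p = 1.89e-88). A larger number of genes near the summit could give this. Among promoter calls with starts of at least 2 genes, both strands were still more frequent in kept peaks (92.6% against 84.9%, odds ratio 2.24, 1.71 to 2.95, exact p = 5.71e-10). On a single strand, at least 2 genes against 1 gave 1.24 (0.951 to 1.62, exact p = 0.0985). Having starts of at least 2 genes rather than 1 therefore does not account for all of the pattern. Calls with 2 and with more genes were pooled, so the number of genes was not held fixed. Whether larger numbers of genes give the rest was not tested.

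Among heptamers outside promoters, AGTATGC had the largest excess in kept peaks on arms 2L, 2R and X, in 10.6% of kept peaks and 3.08% of other calls there. On arms 3L, 3R and 4, which were left out of the choice among 8186 heptamers, it was in 69 of 790 kept peaks (8.73%) and 237 of 8476 other calls (2.80%), an odds ratio of 3.33 (2.48 to 4.42, Fisher's exact test, p = 2.03e-14). The heptamers had been counted on all arms before the arms were split, so the left-out arms are no independent check, and whether the excess holds in other data was not tested. At promoters the same procedure gave ATCGATA, part of the DRE (odds ratio 2.14 on the left-out arms, exact p = 4.49e-14), and then AGTGTTG (2.82, 2.14 to 3.70, exact p = 2.64e-14).

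Among transposable elements, calls were unevenly spread over families. INE-1 insertions held 299 calls, 33.1% of all calls in annotated elements, on 6.27% of their length, or 586 per Mb. In roo, with 12.2% of the length, 6 calls (6.04 per Mb) were found. Windows unique in the assembly (all 32-mers within 100 bp of a position occurring once) made up 40.9% of INE-1 and 0.995% of roo sequence. Both densities are per Mb of all sequence of a family, so the contrast between families cannot be told apart from this difference in unique share. Of the INE-1 calls, 6 were kept.

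Pooled calls, most of them weak, were dense on chromosome 4 and in the unique part of pericentric sequence. Per Mb of unique sequence, calls on chromosome 4 were 3.94 times as dense as on the large arms (3.68 to 4.21). This argues against reads shared between exact copies in the assembly as the whole source of the density. Reads from copies that differ slightly, or from sequence missing from the assembly, were not covered. In pericentric sequence, where 17.6% of positions had a unique window, calls were 2.36 times as dense (2.25 to 2.48), although per Mb of all assembled sequence the ratio was 0.753. Kept peaks per unique Mb were 1.66 times as dense on chromosome 4 (1.27 to 2.13) and 0.796 times in pericentric sequence (0.644 to 0.972), relative to the large arms.

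The share of kept peaks in these regions was smaller than that of the other calls, and 2 explanations of this ratio were tested. On chromosome 4 it reflects denser weaker calls, not fewer kept peaks, since both were denser there than on the large arms. If few promoters there were the whole cause, the ratio outside promoters would be near 1, but the odds ratio was 0.172 in pericentric sequence (0.127 to 0.229) and 0.336 on chromosome 4 (0.221 to 0.491). If reads shared between exact copies in the assembly were the cause, it would be near 1 for calls in unique windows outside promoters. The odds ratios there were 0.147 (0.0936 to 0.220) in pericentric sequence and 0.330 (0.209 to 0.497) on chromosome 4. Copies that differ slightly and sequence missing from the assembly were again not covered. Read length is not given in the sources used here, and the control library was not analysed, so a local bias of the control stays open. No biological explanation was tested.

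For the excess of DRE in kept promoter peaks, lower GC content was tested first. Against 4902 other promoter calls of matched GC (37.3% against 37.0% in kept peaks), DRE was in 11.0% and 6.28% of windows, an odds ratio of 1.84 (1.55 to 2.18, Fisher's exact test, p = 2.19e-12), so GC content does not account for all of it. Since the control octamer had passed too, DRE was also set among 267 octamers of similar frequency in promoter calls. Its odds ratio was at percentile 99.6, and 1 of them was as high. The median of these octamers was 1.28, above 1, so part of any single octamer's excess may be general. Whether ADD1 itself, other factors at the same promoters or their accessible chromatin give the signal cannot be read from these lists, since no other ChIP target was analysed here, and no biological explanation was tested.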
